A study of Streptomyces auratus with 4 samples.

How the data were processed

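Total RNA of bacterial cells had been extracted with a commercial kit, treated with DNase I and made into stranded total RNA libraries, per the labels' protocols. The deposited table holds, per its column headers, 1 value per gene and library in TPM, computed by the authors, together with a product description and KEGG terms. Bowtie2, RSEM, DESeq2 and edgeR are named per the submitters' processing notes, without version or role. The table also gives the authors' group means, which differed from the means of the libraries by at most 0.005 TPM. Read counts and depth were not in the table, and neither a genome build nor gene coordinates were given in the sources used here, so genes were placed only by the order of their ORF numbers and printed without the strain prefix.

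Libraries were grouped by genotype, 2 per group, with no covariate. Genes with a mean of at least 1 TPM over the 4 libraries were tested on log2(TPM + 1) with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend, two-sided). A linear model on log values was used because TPM are not counts. The 2 residual degrees of freedom were supplemented by 4.63 prior degrees of freedom from all genes. Genes at a Benjamini-Hochberg adjusted p under 0.05 were called, and those with an absolute log2 fold change of at least 1 were counted as changed at least 2-fold. The main test was tested on simulated data with 200 changed genes among 5631 in 10 simulations: it recovered 13.7% of genes changed 2-fold and 90.8% of genes changed 4-fold, and 4.9% of its calls were false. Most 2-fold changes would therefore be missed with 2 libraries per group. Simulated errors were independent and normal, drawn from the spread that limma had fitted. Changed genes were taken only from those with a mean above 2 on the log2(TPM + 1) scale. The share of false calls is thus nearly set by the threshold and says little about errors shared between genes of the real libraries.

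Named genes, 69 in all, were picked by a rule fixed before the data were seen. It took the 12 highest and 12 lowest log2 fold changes among called genes that met 3 conditions. These were a product description other than hypothetical, a mean of at least 10 TPM in the higher group, and both libraries of a group above both of the other. It also took up to 4 members of each called list or list with at least 3 called members, and up to 4 genes of each of the 5 longest runs. A total of 26 gene lists had been written beforehand as patterns on product descriptions. The patterns also match some other products, such as an S6 modification protein (orf03510) among ribosomal proteins and a YbaK-type protein (orf00649) among aminoacyl-tRNA synthetases. These lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over the 26 lists. Their members were also adjusted over each list alone. The estimated correlation rests on only 2 residual degrees of freedom, so a list not called with it is left undecided. Runs of at least 5 genes called in the same direction, with at most 1 other tested gene between consecutive members, were compared with 10000 random placements of the same calls. The division of the polyketide block into stretches, the comparison of its lowered and core genes, the KEGG pathways with at least 10 tested genes and the families of Plm and Tpa genes were chosen only after the results had been seen. So were 2 further lists, on DNA replication and on the transcription and translation machinery outside the ribosome, which were adjusted over these 2.

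Alternatives tried were pseudocounts of 0.1, 0.5 and 5, no filter and a filter at 10 TPM, libraries centred on the median, trimmed-mean scaling, quantile normalization, TPM recomputed without the 20 most abundant genes, eBayes without trend and robust, a replicate block, leaving out each library, runs without gaps or of at least 3 genes, and genes listed at 0 in any library left out. The last was added after the data had been seen. Genes under the filter were not tested, and no library was left out of the main tests.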

Results

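RNA from bacterial cells of Streptomyces auratus, strain CIBA Tu 96, was sequenced in 4 libraries, 2 from a lysR2 knockout mutant and 2 from the wild type. The deposited table gave the expression of 7582 genes in TPM, and 248 of these were listed at 0 in every library. TPM keep no record of sequencing depth, so depth was unknown. The listed values added up to 694373 and 720340 in the knockout libraries and to 727722 and 724522 in the wild type libraries. These are 69.4% to 72.8% of the full TPM scale, and what made up the rest was not analysed here. A single hypothetical protein gene, orf01800, held 28.9% and 28.4% of the listed TPM in the knockout and 38.6% and 37.8% in the wild type. The 20 most abundant genes together held 64.6% and 66.7% against 72.0% and 74.6%. Across genes, log2 values correlated at r = 0.966 between the knockout libraries, at 0.977 between the wild type libraries, and at 0.934 to 0.948 between groups. Nothing in the labels says that replicates came from separate cultures, so the p-values of limma and fry rest only on the spread between these 4 samples. Those of camera at the preset correlation and of the runs compare genes with other genes. None of them reaches beyond these 4 samples. Fold changes are log2 differences (knockout minus wild type) ± standard error, with n = 2 per group throughout. They were taken on the log2(TPM + 1) scale, which understates the change of genes with low TPM. Levels are mean TPM ± standard deviation.

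No gene in the table was named lysR2, so the knockout could not be checked at its own gene. The products of 29 genes were described as LysR-family regulators, a large family of bacterial DNA-binding proteins, and 23 of them were expressed highly enough to test. None of the 23 passed the test (limma, smallest adjusted p = 0.0882), and 7 had an unadjusted p under 0.05. A replicate block, for which no pairing is stated, called some of them, as given below. Without knockout replicate 2, 1 was called higher (orf04666, 1.03 ± 0.25, limma adjusted p = 0.029). Their knockout levels ran from 64.7% of wild type for orf04357 to 272% for orf03749. The first stood at 13.2 ± 0.771 TPM in the wild type and 8.56 ± 0.665 in the knockout, the second at 0.755 ± 0.134 and 2.06 ± 0.389. As a list they did not pass the test against other genes (median log2 fold change 0.02, mean 0.22, camera adjusted p = 0.983). None of them is taken here for lysR2. The sources used here do not say whether lysR2 encodes a protein of this family or where it lies.

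The largest fall among named genes was that of a secreted protein gene, orf00354, from 562 ± 90.6 to 32.9 ± 11.5 TPM (-4.09 ± 0.28, limma adjusted p = 0.00362). Streptogrisin-D, a secreted serine protease (orf06825), fell from 145 ± 55.9 to 11.5 ± 0.806 TPM (-3.50 ± 0.29). A transcriptional regulator, orf04578, fell from 311 ± 61.3 to 38.5 ± 2.28 TPM (-2.97 ± 0.21). A Rieske iron-sulfur protein (orf06741, -2.60 ± 0.37) and an acetyl-CoA synthetase, which activates acetate (orf04419, -2.37 ± 0.22), also fell. So did an RpiR-family regulator (orf03130, -2.25 ± 0.24), a regulatory protein (orf02721, -2.25 ± 0.25) and a serine/threonine protein kinase (orf04865, -2.19 ± 0.18). A GntR-family regulator (orf04416) rose from 0.95 and 0.65 TPM in the wild type libraries to 13.75 and 23.53 in the knockout (3.41 ± 0.30). Both subunits of DNA gyrase, which introduces negative supercoils into DNA, rose (A, orf03742, 22.7 ± 3.39 to 129 ± 2.48 TPM, 2.46 ± 0.20, and B, orf03741, 2.07 ± 0.18). The arginine repressor (orf06218) rose from 7.50 ± 1.80 to 33.7 ± 12.3 TPM.

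**Figure D1:**
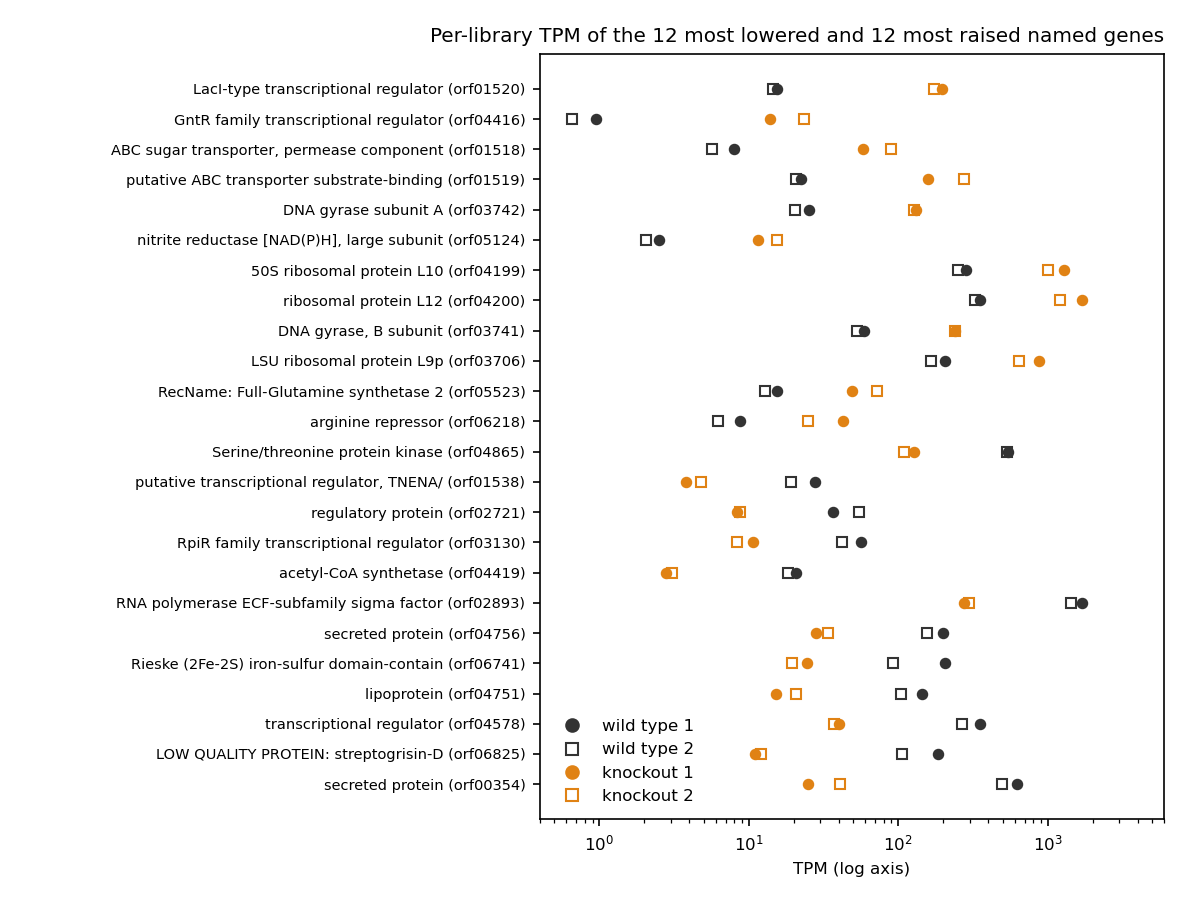
TPM (log axis) in each library of the 12 most lowered and the 12 most raised genes under the rule for named genes, which left out hypothetical proteins here. Wild type is in dark grey and lysR2 knockout in orange, with circles for replicate 1 and open squares for replicate 2. No error bars are drawn because both libraries are shown. The 2 groups lie apart in every gene because the rule required it. Examples are the secreted protein gene orf00354 (625.8 and 497.7 TPM in the wild type, 24.77 and 40.99 in the knockout) and the LacI-type regulator orf01520 (15.43 and 14.6, 196.01 and 174.61).

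Over the whole table, 413 of 5631 tested genes changed (limma, adjusted p under 0.05), 264 higher and 149 lower. Of these, 359 changed by at least 2-fold, 221 higher and 138 lower. All 413 had both libraries of one group above both of the other, and 1613 genes had an unadjusted p under 0.05. The median log2 fold change of all tested genes was 0.24, and the split between higher and lower genes moved with the scaling of the libraries. The calls were 200 higher and 227 lower with libraries centred on the median, and 142 and 254 with trimmed-mean scaling. They were 162 and 236 with quantile normalization, and 137 and 284 without the 20 most abundant genes. Without knockout replicate 1 the count was 250. Without wild type replicate 1 or 2 no gene passed (limma, smallest adjusted p = 0.0527 and 0.0559), so no single-gene call, here or below, was kept in those 2 settings.

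A block with genes for an aromatic polyketide lay between orf01518 and orf01562 in the numbering of the table. Its limits are those of the called runs, not of an annotated cluster. It holds a product named LlpT (orf01541), a prefix used for the antibiotic lysolipin. All 7 genes at its start, orf01518 to orf01524, rose. They comprised a sugar ABC transporter permease (orf01518, 6.81 ± 1.57 to 73.4 ± 22.2 TPM, 3.23 ± 0.28) and its substrate-binding protein (orf01519, 21.6 ± 1.12 to 216 ± 82.1 TPM, 3.21 ± 0.28). A LacI-type regulator (orf01520) rose from 15.43 and 14.6 TPM in the wild type libraries to 185 ± 15.1 (3.54 ± 0.19, limma adjusted p = 0.00156), and a hypothetical protein (orf01521) from 10.8 ± 0.997 to 176 ± 4.19 (3.91 ± 0.19). The others were a PadR-family regulator (orf01522, 1.43 ± 0.29), a FAD-dependent monooxygenase (orf01523, 1.71 ± 0.25) and a hypothetical protein (orf01524, 1.59 ± 0.24). With trimmed-mean scaling 5 of the 7 were called. Just before them, a sugar hydrolase (orf01516, 0.98 ± 0.23, limma adjusted p = 0.0516) and a sugar transport permease (orf01517, 1.16 ± 0.33, adjusted p = 0.0805) were not called. Whether the sugar transport genes and the LacI-type regulator belong with the polyketide genes was not tested.

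At the other end of the block, 18 of the 20 genes from orf01543 to orf01562 fell, with log2 fold changes from -2.17 to -1.31. They encode 5 O-methyltransferases, 1 other methyltransferase, 2 cytochromes P450, 2 FAD monooxygenases, 3 reductases or dehydrogenases, 1 halogenase, 1 permease, 1 regulator and 2 hypothetical proteins. Enzymes of these kinds commonly decorate polyketide skeletons. The halogenase (orf01558) fell from 90.1 ± 4.25 to 26.0 ± 6.06 TPM (-1.77 ± 0.22), a cytochrome P450 (orf01546) by 2.06 ± 0.32 on the log2 scale and an O-methyltransferase (orf01551) by 2.06 ± 0.33. A 3-oxoacyl-ACP reductase (orf01557, -1.96 ± 0.31), a hypothetical protein (orf01552, -2.17 ± 0.24) and the permease (orf01543, -1.83 ± 0.29) fell as well. The regulator, of the SARP family, whose members activate antibiotic clusters, fell from 52.0 ± 2.28 to 15.3 ± 0.106 TPM (orf01559, -1.70 ± 0.19, limma adjusted p = 0.00907). Not called were a second regulator (orf01545, -1.41 ± 0.39, limma adjusted p = 0.0739) and a reductase (orf01560, 0.06 ± 0.19, adjusted p = 0.869). A hypothetical protein gene next to this stretch, orf01542, stood at -1.46 ± 0.41 (limma adjusted p = 0.0763).

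Between these ends, the genes that build the polyketide chain did not pass the test. Of the 17 genes from orf01525 to orf01541, 16 were not called by limma, with log2 fold changes from -0.34 to 0.34 and none at an unadjusted p under 0.05. These values moved with the library left out, from a median of -0.34 (12 of 16 negative) without knockout replicate 1 to 0.33 (13 of 16 positive) without knockout replicate 2. The median was 0.26 without wild type replicate 1 and -0.18 without replicate 2, and with trimmed-mean scaling it was -0.25, with 15 of 16 negative. The ketosynthase alpha subunit (orf01532) stood at 43.0 ± 9.10 TPM in the wild type and 40.9 ± 17.3 in the knockout (-0.12 ± 0.32, limma adjusted p = 0.847). Its partner, the chain length factor (orf01531), stood at 28.0 ± 8.07 and 29.4 ± 15.1 TPM, and the acyl carrier protein (orf01530) at 67.3 ± 4.81 and 55.1 ± 6.32. The remaining gene, orf01538, described as a transcriptional regulator of the TENA/THI-4 family, fell from 27.56 and 19.21 TPM in the wild type libraries to 3.79 and 4.79 in the knockout. This was 18.35% of wild type (-2.19 ± 0.26, limma adjusted p = 0.0101). In a comparison chosen after the results were seen, the 18 lowered genes of each library were set against the 6 core polyketide genes (orf01529 to orf01534). They lay at a mean log2 difference of -0.67 and -0.56 in the wild type and of -2.39 and -2.48 in the knockout. The difference between groups was -1.83, and a factor common to all genes of a library nearly cancels in it. The 18 genes had been picked because they fell, so this difference was given no test.

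**Figure D2:**
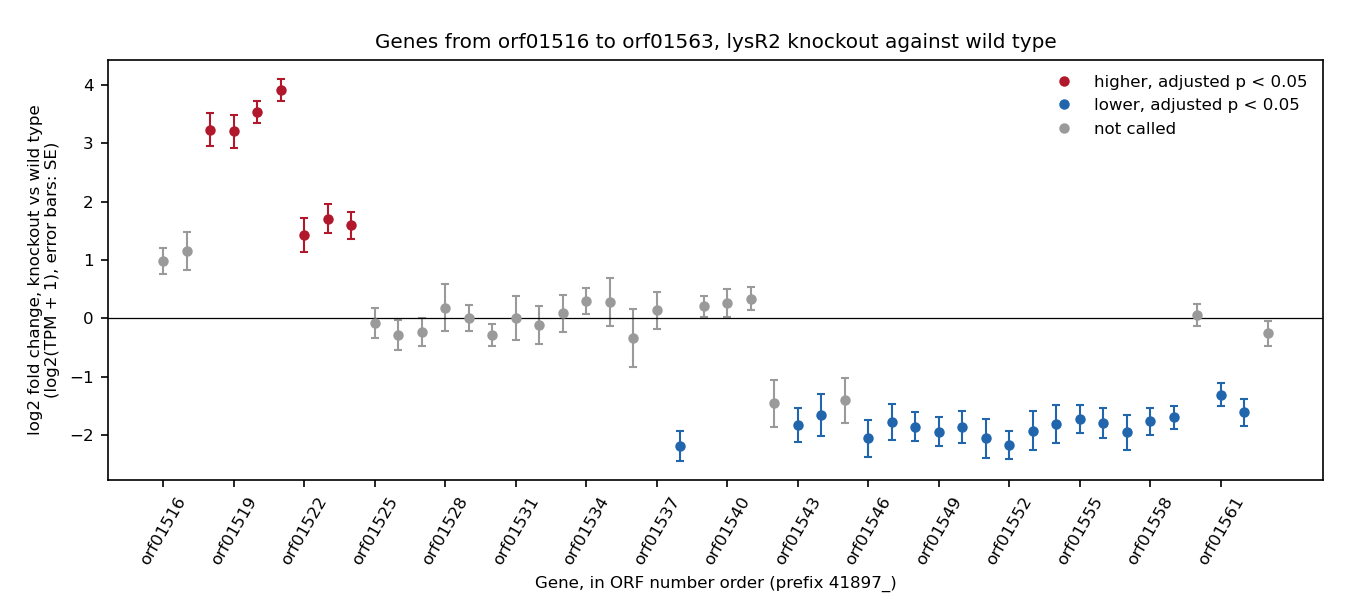
Log2 fold change (knockout against wild type, log2(TPM + 1)) of genes from orf01516 to orf01563 in ORF number order, with red for higher, blue for lower and grey for not called genes; error bars are standard errors from limma, n = 2 per group. The 7 genes at the left rose (mean 2.66), 16 genes in the middle were not called (mean 0.03, with all 4 libraries and TPM as deposited) around the lowered orf01538, and 18 genes at the right fell (mean -1.83).

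Ribosomal protein genes rose together. Of 55 tested, 46 were higher in the knockout, none was lower and 9 were not called, and 53 were higher when adjusted over the list alone. The 9 include orf03510, described as an S6 modification protein and not itself a ribosomal protein. Their median level was 209 TPM in the wild type and 609 in the knockout (median log2 fold change 1.48, quartiles 1.14 to 1.75). The stalk protein L10 (orf04199) rose from 267 ± 22.6 to 1144 ± 194 TPM (2.09 ± 0.20, limma adjusted p = 0.00692), and its partner L12 (orf04200) by 2.07 ± 0.22. L9 (orf03706) rose from 186 ± 28.4 to 762 ± 165 TPM and L30 (orf04231) from 195 ± 3.49 to 776 ± 2.77. S1 (orf05753), which helps mRNA bind the ribosome, stood at 0.14 (limma adjusted p = 0.735). The list was higher than other genes by camera with a preset correlation of 0.01 (adjusted p = 1.85e-25), which treats its genes as nearly independent. It was not with an estimated correlation of 0.586 (camera adjusted p = 0.91). It was not called by the rotation test fry for a shared direction (adjusted p = 0.285), and neither was any other of the 26 lists.

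Aminoacyl-tRNA synthetases, which charge tRNAs with amino acids, had positive log2 fold changes in all 23 tested genes (median 0.59, camera adjusted p = 4.78e-04, adjusted p = 0.91 with an estimated correlation). Those for glycine (orf05091, 39.3 ± 4.03 to 72.3 ± 1.90 TPM, 0.87 ± 0.19, limma adjusted p = 0.0464) and proline (orf02149, 0.93 ± 0.21, adjusted p = 0.0485) rose, and 21 were not called. Adjusted over the list alone, 5 were higher. Both calls were lost without knockout replicate 1 (limma adjusted p = 0.135 and 0.164) and without knockout replicate 2 (adjusted p = 0.0787 and 0.0523). The list's median was 0.30 without the 20 most abundant genes. Neither call was kept with quantile normalization, with trimmed-mean scaling, without the 20 most abundant genes, without a filter or with eBayes without trend.

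Called genes lay side by side more often than under random placement of the calls. Runs of at least 5 neighbouring genes called in the same direction took in 62 genes in 6 runs, 4 higher and 2 lower. In a permutation test, 10000 random placements of the same calls gave at most 10 genes in runs (permutation p = 1e-04, the smallest possible). The placements treat every gene as independent, so the test cannot tell a shared change of neighbouring genes from an error that they share. The longest run held 19 ribosomal protein genes from orf04213 to orf04232 (median 1.63), among them L15 (orf04232, 463 ± 2.80 to 1801 ± 150 TPM, 1.95 ± 0.18), L5 (orf04225, 1.92 ± 0.22) and S5 (orf04230, 1.80 ± 0.20). A run of 6 genes, orf04237 to orf04242, held S4 (orf04240, 1.85 ± 0.19), L17 (orf04242, 1.85 ± 0.19), S11 (orf04239, 1.59 ± 0.20), S13 (orf04238, 1.40 ± 0.23) and the RNA polymerase alpha subunit. A run of 5, orf04196 to orf04202 (median 1.49), held L10, L12 and the RNA polymerase beta' subunit. The 2 ends of the polyketide block made up a raised run of 7 and the lowered run of 18. The other lowered run, of 7 genes from orf04750 to orf04756 (median -1.94), included genes for exported proteins. A lipoprotein (orf04751) fell from 124 ± 27.8 to 17.9 ± 3.74 TPM (-2.72 ± 0.25), and 2 secreted proteins (orf04756, -2.48 ± 0.22, and orf04755, -1.94 ± 0.26) and a hypothetical protein (orf04752, -2.10 ± 0.22) fell too. The runs held 121 genes without knockout replicate 2 and none without either wild type library.

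Genes of nitrogen metabolism were among those that rose. Of 21 tested, 7 were higher and none lower, and 12 were higher over the list alone (median log2 fold change 0.80, camera adjusted p = 0.00135, adjusted p = 0.91 with an estimated correlation). The large subunit of nitrite reductase, which makes ammonium (orf05124), rose from 2.28 ± 0.311 to 13.4 ± 2.65 TPM (2.13 ± 0.24, limma adjusted p = 0.0093). Glutamine synthetase 2 (orf05523), which fixes ammonium into glutamine, rose from 14.0 ± 1.82 to 60.7 ± 16.6 TPM (2.02 ± 0.25), and an enzyme described as type I (orf05489) by 1.51 ± 0.22. A more abundant glutamine synthetase I gene, orf05537, was not called (93.2 ± 16.1 to 151.7 ± 9.47 TPM, 0.71 ± 0.20, limma adjusted p = 0.083). The urease alpha subunit (orf00365) rose by 1.67 ± 0.31. The count was 4 with trimmed-mean scaling and without the 20 most abundant genes, where the median was 0.51. Urease was not called without knockout replicate 2 (limma adjusted p = 0.0574) or with any of the 4 other scalings, and the list was not called with a filter at 10 TPM (camera adjusted p = 0.0554).

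In amino acid biosynthesis 8 of 61 genes were higher and none lower, and 20 were higher over the list alone (median 0.51, camera adjusted p = 4.78e-04, adjusted p = 0.91 with an estimated correlation). Genes for both subunits of 3-isopropylmalate dehydratase, an enzyme of the leucine pathway, rose (large, orf02262, 1.51 ± 0.23, and small, orf02260, 18.5 ± 0.686 to 54.4 ± 3.51 TPM). Less abundant genes with such descriptions were not called (orf00732, 0.36 ± 0.24, orf00733, 0.15 ± 0.26, and orf00735, 0.98 ± 0.28, limma adjusted p = 0.351, 0.749 and 0.0796). A chorismate mutase of the phenylalanine and tyrosine pathway (orf03029, 1.30 ± 0.22) and the regulatory subunit of acetolactate synthase, which starts branched-chain synthesis (orf02304, 1.26 ± 0.20), rose as well. Other genes described as chorismate mutase were not called (orf01166, 0.51 ± 0.21, orf06628, 0.55 ± 0.28, and orf05988, 0.42 ± 0.41, limma adjusted p = 0.172, 0.248 and 0.543). The call of orf03029 was lost without knockout replicate 1 (1.33) and without knockout replicate 2 (1.28), and the list held fewer called genes without knockout replicate 1. Without the 20 most abundant genes it held 5, with a median of 0.23, and with a filter at 10 TPM or robust eBayes 14 and 15.

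In the respiratory chain and ATP synthase none of 36 genes was called by limma, over all genes or over the list alone, and 15 had an unadjusted p under 0.05. As a list they were higher than other genes, with 35 positive log2 fold changes (median 0.50, camera adjusted p = 0.00185, adjusted p = 0.91 with an estimated correlation). Cytochrome c oxidase subunits II, I and III, of the terminal oxidase, stood at 1.09 ± 0.33 (orf05575), 1.08 ± 0.28 (orf05576) and 0.94 ± 0.23 (orf05580). The ATP synthase epsilon chain (orf02469) stood at 0.79 ± 0.22. Calls were made under some alternatives, 3 without knockout replicate 2, 3 with robust eBayes, 3 with genes listed at 0 left out and 5 with a filter at 10 TPM. A replicate block called more, as given below. The median was 0.21 with trimmed-mean scaling and 0.20 without the 20 most abundant genes, where camera still called the list (adjusted p = 0.00222 and 0.00501).

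Sigma factors, which direct RNA polymerase to promoters, were lower than other genes as a list (median -0.02, camera adjusted p = 0.00963, adjusted p = 0.91 with an estimated correlation). Of 25 tested, 3 fell and none rose, with the same counts over the list alone. The ECF-type gene orf02893 fell from 1564 ± 190 to 288 ± 16.4 TPM (limma adjusted p = 0.00517), the ECF-type gene orf04295 by 1.58 ± 0.21 and a gene described as SigL (orf04675) from 99.4 ± 17.1 to 36.0 ± 2.18 TPM (-1.43 ± 0.21). A more abundant gene described as sigma L (orf03553, 396.9 ± 54.02 to 361.7 ± 24.36 TPM, -0.13 ± 0.19) was not called (limma adjusted p = 0.7005). Neither was a SigL-like gene (orf04559, -0.02 ± 0.19, limma adjusted p = 0.968). SARP and LuxR-type regulators were also lower (median -0.09, camera adjusted p = 0.0262, adjusted p = 0.91 with an estimated correlation). Of 19 tested, 2 fell and none rose, or 2 and 1 over the list alone. They were the SARP gene of the polyketide block and a LuxR-family gene (orf00473, 4.76 ± 1.27 to 1.10 ± 0.127 TPM, -1.44 ± 0.26). Fatty acid oxidation was lower too (median -0.01, camera adjusted p = 0.0157, adjusted p = 0.91 with an estimated correlation). Of 27 tested, 2 fell and none rose, with the same counts over the list alone. They were neighbouring genes for an enoyl-CoA hydratase/isomerase (orf01035, 9.46 ± 0.870 to 2.47 ± 0.495 TPM, -1.60 ± 0.24) and an acyl-CoA dehydrogenase (orf01034, -1.26 ± 0.23). The 3 medians were further from 0 under other scalings. Without the 20 most abundant genes they were -0.34 for sigma factors (20 of 25 negative), -0.38 for SARP and LuxR regulators and -0.22 for fatty acid oxidation (22 of 27 negative, 4 called lower). Without wild type replicate 1 those of sigma factors and fatty acid oxidation were 0.04 and 0.11, and without knockout replicate 2 both were 0.04. The SARP and LuxR list was not called without knockout replicate 1 (camera adjusted p = 0.0569), without wild type replicate 2 (0.0674) or with a filter at 10 TPM (0.109), nor was fatty acid oxidation without a filter (0.142) or at 10 TPM (0.0554). The calls of orf00473 and orf01034 were lost without knockout replicate 1 (limma adjusted p = 0.0629 and 0.1).

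**Figure D3:**
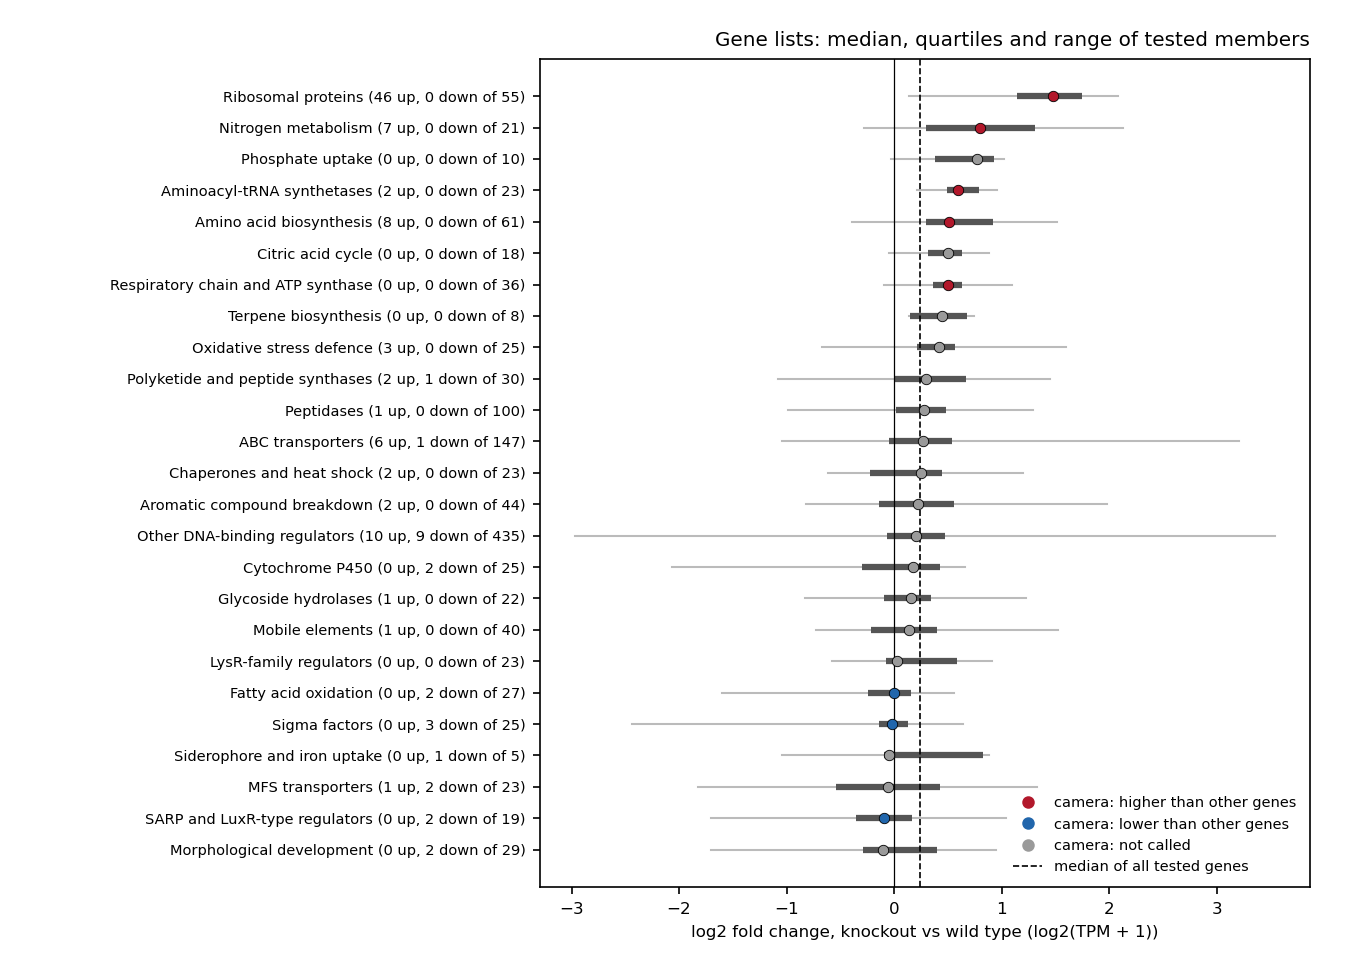
Log2 fold changes (knockout against wild type, log2(TPM + 1), n = 2 per group) of the tested members of each gene list except the hypothetical proteins, as median (dot), quartiles (thick bar) and range (thin line), with red and blue dots for lists called higher or lower by camera at a preset correlation and grey for the rest; the dashed line is the median of all tested genes (0.24). Ribosomal proteins lay farthest to the right (median 1.48), followed by nitrogen metabolism (0.80), whereas the lists called lower had medians of -0.09 to -0.01 with TPM as deposited.

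Further lists were not called by camera, but most held single genes that changed. In oxidative stress defence 3 of 25 rose. They were a superoxide dismutase, which removes superoxide (orf02553, 186 ± 11.2 to 566 ± 40.4 TPM, 1.60 ± 0.18), and 2 genes of peroxide removal (orf02763, 1.38 ± 0.18, and orf02765, 1.18 ± 0.22). Among 30 polyketide and peptide synthase genes 2 non-ribosomal peptide synthetases rose (orf00251, 1.43 ± 0.28, and orf00249, 1.20 ± 0.26) and an acyl carrier protein fell (orf05946, 48.2 ± 6.17 to 22.2 ± 2.04 TPM, -1.08 ± 0.21). Of 147 ABC transporter genes 6 rose and 1 fell with TPM as deposited. The counts were 3 and 2 both with libraries centred on the median and with quantile normalization, 2 and 3 with trimmed-mean scaling, 1 and 2 without the 20 most abundant genes, and 2 and 0 without knockout replicate 1. A substrate-binding protein (orf00958, 13.3 ± 2.35 to 33.4 ± 7.98 TPM), an ATP-binding subunit (orf02451, 1.15 ± 0.21) and a permease (orf00351, 1.12 ± 0.21) were among the raised. Of 23 MFS transporters 1 rose (orf00852, 1.14 ± 0.26) and 2 fell, among them orf02001 (-0.99 ± 0.22). Without knockout replicate 1 the calls of orf00249, orf00251, orf00351, orf00852, orf02001, orf02451, orf02765 and orf05946 were lost, and without knockout replicate 2 those of orf00958 and orf02001. Neither orf00852 nor orf00958 was called with any of the 4 other scalings, under which no MFS transporter was higher and 3 or 4 were lower. With trimmed-mean scaling the calls of orf00249 and orf00351 were lost as well (limma adjusted p = 0.0517 and 0.055). Without the 20 most abundant genes those of orf00249, orf00251, orf00351 and orf02451 were lost (adjusted p = 0.0707, 0.0605, 0.0615 and 0.0513). Without a filter those of orf00249, orf00251, orf00852, orf00958 and orf02001 were lost, and with a pseudocount of 5 or eBayes without trend those of orf00852 and orf02001.

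The remaining lists held few called genes, and the direction of the calls moved with the scaling in some of them. Other DNA-binding regulators had 10 higher and 9 lower of 435, and hypothetical proteins 17 and 15 of 451. The regulators had 9 and 16 with libraries centred on the median, 5 and 17 with trimmed-mean scaling, 6 and 15 with quantile normalization, 5 and 18 without the 20 most abundant genes, and 4 and 5 without knockout replicate 1. Hypothetical proteins had 10 and 22 without the 20 most abundant genes, 30 and 15 without knockout replicate 1 and 30 and 28 without knockout replicate 2. Cytochromes P450 had none higher and 2 lower of 25, and morphological development none and 2 of 29. With the 4 other scalings both again had none higher, with 3 or 4 lower P450 genes and 3 lower developmental genes. Chaperones had 2 higher of 23, breakdown of aromatic compounds 2 of 44, peptidases 1 of 100, glycoside hydrolases 1 of 22 and mobile elements 1 of 40, with none lower. Without the 20 most abundant genes, however, chaperones had none higher and 3 lower, aromatic breakdown 2 and 3, peptidases 1 and 1, glycoside hydrolases none and 2, and mobile elements none and none. With trimmed-mean scaling these were none and 3, 1 and 2, 1 and 1, none and 2, and none and none. Without knockout replicate 1, chaperones had 1 higher, peptidases 2 higher and 1 lower, glycoside hydrolases none, mobile elements 2 higher and morphological development 1 lower, and mobile elements also had 2 higher without knockout replicate 2. Iron uptake had 1 lower of 5, also with the 4 other scalings, and none without either knockout library. None of 10 phosphate uptake genes (median 0.77, camera adjusted p = 0.0505, 5 higher over the list alone), 18 genes of the citric acid cycle (median 0.50, camera adjusted p = 0.072) and 8 of terpene biosynthesis (median 0.45) was called by limma. Of these, 6, 8 and 3 had an unadjusted p under 0.05, and the 3 medians stayed above 0 with the 4 other scalings, where again none was called. With a filter at 10 TPM 3, 4 and 1 were called higher, and 3 phosphate genes with robust eBayes, 3 with genes listed at 0 left out and 2 without knockout replicate 2. Robust eBayes also called 1 gene of the citric acid cycle. Camera compares a list with all other genes, so its direction could be lower where the list's own median was above 0. This held for chaperones (median 0.25), aromatic breakdown (0.23), other regulators (0.20), cytochromes P450 (0.18, mean -0.05), hypothetical proteins (0.16), glycoside hydrolases (0.15) and mobile elements (0.14). For iron uptake, also lower, the median was -0.05 and the mean 0.10.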

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

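All alternatives were planned before the data were seen, except that leaving out genes listed at 0 in any library (588 called genes) was chosen only after the results. No named gene changed sign and no called list changed its camera direction under any setting. The balance of calls turned, however, from 264 higher and 149 lower to mostly lower with libraries centred on the median (200 and 227), trimmed-mean scaling (142 and 254), quantile normalization (162 and 236) and without the 20 most abundant genes (137 and 284). The medians of 2 lists called lower changed sign, fatty acid oxidation from -0.01 to 0.09 without a filter and 0.11 without wild type replicate 1, and sigma factors from -0.02 to 0.04 without that library. Without knockout replicate 2 both medians were 0.04. Of the values of 69 named genes under 17 settings (fewer genes at 10 TPM), 963 were the same, 15 stronger and 187 weaker, 130 of the weaker without a wild type library, and 50 of the 65 called named genes kept their call in every setting with both wild type libraries. Of 144 list values 130 were the same and 14 weaker. Leaving out 1 library in turn gave 0 to 508 called genes, 0 to 485 changed at least 2-fold, 0 to 121 genes in runs and 7 to 12 called lists. This leaves a group with 1 library, assumed to vary like the other group, and without a wild type library the spread comes from the knockout pair alone. An unadjusted p under 0.05 was found for 1061 genes without wild type replicate 1 and 849 without replicate 2. With a pseudocount of 5, which shrinks the fold of low genes by construction, 235 genes changed at least 2-fold. A filter at 10 TPM, with 2372 genes tested, gave 140 genes in runs, and counting runs of at least 3 genes, a wider definition, 137. Camera with an estimated correlation called 0 lists, and none had an unadjusted p under 0.05. Each correlation was estimated from the 2 residual degrees of freedom of these libraries, which leaves this form little power. Its p-values therefore cannot decide for or against a shift of a list. Replicates share the numbers 1 and 2, and the replicate 1 libraries carry the similar column names A1 and A2, but nothing states that they pair. Between groups, libraries of equal number correlated at r = 0.942 and 0.948, and those of unlike number at 0.934 and 0.935. With 2 pairs the deviations of equal numbers correlated at 0.378, so an effect shared by replicate number is left open. A replicate block gave 1541 called genes, 1157 higher and 384 lower, and 387 genes in runs. It called 6 LysR-family genes higher and 1 lower (orf04357, -0.57, limma adjusted p = 0.0454) and 13 of 36 respiratory genes higher. The cause was not tested. The 2 other ways to split the libraries in pairs gave 0 calls each. In both, the difference between genotypes falls within each group and widens its spread, so these counts do not exclude a replicate effect. No gene was named lysR2, so its level gave no value under any alternative. Depth is unknown, so its limit on low genes could not be stated.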

Other observations

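The gene families of this paragraph and the KEGG pathways were chosen only after the results were seen. Genes with Plm names, which are used for the polyketide phoslactomycin, lay between orf00371 and orf00402, and 7 of 26 tested were higher in the knockout, none lower, with positive log2 fold changes in all 26 (median 0.95). PlmT4 (orf00385) went from 9.84 ± 0.0778 to 37.0 ± 7.09 TPM (1.80 ± 0.22, limma adjusted p = 0.0122, n = 2 per group), Plm4 (orf00377) from 1.97 ± 0.354 to 7.81 ± 2.50 TPM (1.54 ± 0.28) and Plm8 (orf00375) from 5.62 ± 0.820 to 17.7 ± 2.25 TPM. The regulator-named PlmR1 (orf00396) stood at 0.13 ± 0.20 (limma adjusted p = 0.7). The 7 calls became 1 without knockout replicate 1, 13 without knockout replicate 2 and 0 without either wild type library. None of 8 genes with Tpa names, which are used for a thiopeptide, was called by limma, and none had an unadjusted p under 0.05. Their first gene, TpaA (orf04367), was among the most abundant of all, at 6516 and 17508 TPM in the wild type and 6935 and 9997 in the knockout.

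Beside the lowered streptogrisin-D gene, a hypothetical protein gene, orf06826, was listed at 0 in both knockout libraries and at 8.36 and 12.56 TPM in the wild type. In all, 10 called genes were listed at 0 in both libraries of a group, 3 in the knockout and 7 in the wild type. Among developmental genes a WhiB-family regulator (orf02744) fell from 57.0 ± 0.156 to 29.7 ± 5.44 TPM (-0.93 ± 0.21, limma adjusted p = 0.0495, n = 2 per group) and a sporulation-associated protein gene fell (orf06189, -1.71 ± 0.24, adjusted p = 0.0145). AdpA, a regulator of development and antibiotic synthesis, stood at 0.28 ± 0.20 (orf04814, limma adjusted p = 0.378). Of 18 DNA replication genes 2 rose, the gyrase subunits (median 0.31, camera adjusted p = 0.186, adjusted p = 0.47 with an estimated correlation). Of 83 KEGG pathways, camera at the preset correlation called 10, among them the ribosome (adjusted p = 3.55e-25), oxidative phosphorylation (2.40e-04), arginine biosynthesis (0.0119, 6 of 28 genes called higher) and, lower, starch and sucrose metabolism (0.012, median -0.12). None was called with an estimated correlation (adjusted p = 0.977 for the ribosome), and none had an unadjusted p under 0.05.

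The tests of TPM share, of a deleted gene and of the 15 genes away from the ribosomal runs, below, were chosen only after the results were seen, whereas the prediction on growth state was written before its test, with 2 genes of its list (the RNA polymerase alpha and beta' subunits) already seen in the runs of ribosomal genes. The rise of ribosomal protein genes could come from TPM share set free by orf01800 and a few other abundant genes, which held less of it in the knockout. That would leave the list near 0 once the 20 most abundant genes were left out and each library was centred on its median, but the median log2 fold change was then 1.255 (quartiles 0.901 to 1.507), which argues against share as the whole cause. A faster-growing or younger state of the sampled knockout cells would also raise the transcription and translation machinery outside the ribosome. Its 22 tested genes had a median of 0.789, 10 were higher and none lower, among them elongation factor Tu (orf04207, 1.43). The median exceeded that of 99.99% of random lists, as did that of the 15 genes outside orf04196 to orf04242 for 99.72% (median 0.718). Random lists were drawn gene by gene, so they leave out correlation between genes, and these shares may be too high. The DNA replication list, by contrast, had a median of 0.311, above that of only 66.97% of random lists. The rotation test fry for a shared direction called both lists (adjusted p = 0.0319 over these 2). It called none of the 26 planned lists (smallest fry adjusted p = 0.285). Fry tests a list against no change and not against other genes, whose median was 0.24. Its call of these lists therefore does not set them apart from other genes. For the machinery the prediction was met (camera adjusted p = 0.47 with an estimated correlation). The other scalings gave 3 to 8 higher genes and a median of 0.471 at the lowest, and without knockout replicate 1 limma called none, with a median of 0.761 and 12 genes at an unadjusted p under 0.05, and whether lysR2 acts on these genes itself was not tested.

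The single lowered gene inside the part of the polyketide block that was not called, orf01538, could be the deleted gene itself. Its knockout level was 18.35% of wild type, against 81.51% to 137.55% in its 16 neighbours, but that contrast is the pattern itself and lends the explanation no weight. A gene removed in full would leave next to no reads, whereas orf01538 kept 3.79 and 4.79 TPM in the knockout libraries. In comparison, 3 called genes were listed at 0 in both of these libraries. The values cannot tell a partial deletion of orf01538 from lowered expression. Of the 4 other regulators of the block 2 were low as well, orf01545 at 21.4% (not called) and the SARP gene orf01559 at 29.37% of wild type, and 2 were raised, orf01520 at 1234% and orf01522 at 268%. Of 458 tested regulator genes of the genome, 1 stood at a lower percent than orf01538 (orf04578, 12.39%), and 3 fell further on the log2(TPM + 1) scale (orf04578, orf03130 and orf02721). The table calls no gene lysR2, and the sources used here do not place it in or outside this block, so the values cannot tell whether any of the lowered genes is the deleted gene or a target.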
